A study of Mus musculus with 4 samples.

How the data were processed

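C2C12 cells are a mouse myoblast line that forms myotubes when serum is lowered. Per the labels' protocols, the cells were grown in 10% fetal bovine serum and then differentiated for 6 days, with 20 nM GDF8 (recombinant mouse myostatin, a TGF-beta family ligand) added every 24 h or with no addition. The labels disagree on the horse serum of the differentiation medium: the growth protocol gives 2% and the source names give 10%. Total RNA was amplified, labelled with Cy3 or Cy5 and hybridised to 4 two-colour Agilent whole mouse genome arrays, each of which held 1 GDF8 and 1 untreated RNA. The labels call the arrays biological replicates 1 to 4, without saying how the cultures were kept apart. GDF8 was in Cy5 (red) on the arrays of replicates 2 and 3 and in Cy3 (green) on those of replicates 1 and 4, so that 2 arrays ran in each orientation. All 4 arrays lay on 1 slide, and no batch term was possible.

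The deposited scanner files give, per the file headers, spot intensity (mean signal and median local background) for each channel and a log10 ratio of red over green, as written by Agilent Feature Extraction 9.1.1.1 from array design 014868. Per the series' design text, the authors exported these data to GeneSpring GX, filtered on present and marginal flags, and used an unpaired test with p under 0.05 and a fold over 1.6. The authors' deposited value table holds log2 ratios. Its scale and direction were found from the scanner files: at a tolerance of 0.001, it equalled the log2 ratio of the processed red and green signals, turned to GDF8 over untreated, in 100% of the 40929 probes with a single spot. Its columns were not centred, with medians of 0.14, -0.09, -0.11 and 0.09 for replicates 1 to 4. No column of that table was without a sample. The deposited other columns are flags of saturation, outliers and signal well above background.

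Each array held 45018 spots, of which 43379 were not controls. The share of such spots saturated in red was 11.1%, 12.1%, 10.5% and 9.20% for replicates 1 to 4, and in green 5.49%, 4.11%, 4.89% and 0.74%. Between 63.3% and 78.8% of these spots were well above background in a channel. Precision is limited by the number of arrays.

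Mean signals were background-corrected by normexp with an offset of 50 and normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots flagged as outliers were left out and spots of 1 probe were averaged, which left 646 of 41174 probes without a value on at least 1 array. A probe entered if it was well above background, in the channel that held the RNA, on all 4 arrays of GDF8 or of untreated cells; 26577 probes passed. The brightest probe on average stood for a gene, which gave 17444 features, of which 13878 had a gene symbol. Names came from a RefSeq list of gene names for assembly GRCm38.p6, used for names alone. By accession 24375 probes were named, by current symbol 6301 and by synonym 2426, and 8072 kept the name in the files. Dimmer probes of Col6a2 (0.17), Id4 (-0.26), Il15 (-0.27), Jag1 (0.19) and Spsb1 (0.22) gave smaller ratios than those reported, with the same sign. No coordinates are given, since the sources used here state no genome build for the array.

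Log ratios were fitted in limma with a term for GDF8 and a term for the dye effect of each probe, and p-values were adjusted by Benjamini-Hochberg over all 17444 features at a threshold of 0.05. Each ratio lies within an array, so the array is the block. An exact test of sign changes over 4 arrays cannot give a two-sided p under 0.125, so single genes rest on the variance that limma shares across genes. Standard errors of log2 values, where given, are from that fit unless another is named. Where a probe was saturated in a whole group, no fold is given.

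Before the data were examined, 21 gene lists with 546 different genes were fixed, of which 540 had a probe. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes to be named were also fixed then: Mstn in any case, the 12 largest rises and 12 largest falls with an adjusted p under 0.05 and the same sign on all 4 arrays, and up to 4 measured members of each list with the smallest p. A gene named outside this rule is said to be so, and some values of single genes are not reported here.

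The fit was tested on simulated ratios for this comparison, drawn for the 17444 features with the estimated dye effects and variances. Of 67 genes changed 1.5-fold 89.6% were recovered, of 67 changed 2-fold 98.5%, and of 66 changed 3-fold 100%, and 21 of 17204 unchanged features were called. That simulation gives each array independent noise.

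Alternatives fixed beforehand covered background correction, an offset of 10, median centring, Aquantile, the filter on dim probes, the dye term, unpaired single-channel values, every probe on its own, the methods' t-test, a fold threshold of 1.6, the authors' deposited log2 table, leaving out each array, and each dye orientation alone. A probe choice that avoids saturated probes, and averages of arrays 1 and 2 and of arrays 3 and 4, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and tables were read with data.table (version 1.17.8).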

Results

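Gene expression was measured in C2C12 mouse myoblasts after 6 days of differentiation with or without 20 nM GDF8 (myostatin), on 4 two-colour arrays that each compared 1 treated with 1 untreated biological replicate. The comparison asks which transcripts differ when myostatin is present during differentiation. Gene values below are log2 ratios of GDF8 over untreated cells, and ± gives the standard error from limma (n = 4 arrays) where printed. List medians carry no standard error. Adjusted p-values of genes are limma's, over 17444 features unless another fit is named.

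After differentiation in GDF8, 14 of 50 sarcomere genes and 11 of 23 genes of muscle energy metabolism were lower and 15 of 41 cell cycle genes were higher, with 0 of each list past the threshold the other way. These lists passed camera with a preset correlation, but not with an estimated one (adjusted p = 0.55 for each). Before adjustment the latter p-values were 0.15, 0.081 and 0.052. The estimated correlations of these lists were 0.27, 0.23 and 0.16, above the preset 0.01, so camera's p-values at the preset may be too small. With probes never saturated, the estimated correlation was -0.063 for TGF-beta-induced genes and -0.041 for myogenic transcription factors, below the preset 0.01. Camera's unadjusted p still rose, from 0.00047 to 0.064 and from 0.0082 to 0.11. This argues against correlation between genes as the cause in those lists with probes never saturated. With the brightest probes the estimates for TGF-beta-induced genes and myogenic transcription factors were 0.13 and -0.059. With an estimated correlation camera takes its degrees of freedom from the fit, which left 2 with either probe choice. Its p therefore rises even without correlation, and not passing there decides little about a list. For lists with a positive estimate, as above, the share due to correlation was not tested, nor was the cause for fry. The deepest fall was in Myl2, a regulatory myosin light chain, at -2.01 ± 0.19 or 4.02-fold lower (adjusted p = 0.0096), with 1 untreated channel saturated. Myosin-binding protein C genes fell with it: Mybpc2 by 3.20-fold (-1.68 ± 0.18) and Mybpc3 by 2.79-fold (-1.48 ± 0.12). Ckmt2, the mitochondrial creatine kinase of muscle, fell 3.20-fold (-1.68 ± 0.10). Among rises, Ccnb1, the cyclin that drives entry into mitosis, was 1.93-fold higher (0.95 ± 0.09, adjusted p = 0.0083), and Cenpa, the histone variant of centromeres, was 1.91-fold higher (0.93 ± 0.09).

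In all, 150 features were higher and 402 were lower after GDF8. Of these, 61 and 278 passed 1.6-fold, and 3 and 89 passed 2-fold. The same sign was seen on all 4 arrays in 545 of the 552, which is no independent evidence, since the same arrays chose these features. Without replicate 1, 95 were higher and 322 lower, and without replicate 4, 8 and 76, with the same range of standard errors (0.104 to 0.445). Without replicate 2, 12 were higher and 107 lower, and without replicate 3, 107 and 293, again with the same range (0.139 to 0.334). This argues against lost precision as the source of the differences within each pair of fits. The number of calls thus leaned on replicates 4 and 2. Without the dye term 66 and 274 passed, without pairing by array 58 and 265, and with arrays 1 and 2 and arrays 3 and 4 averaged, a choice made after seeing the data, 23 and 172.

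The 12 largest falls also held genes outside the contractile apparatus. Tspan13, a tetraspanin, fell 3.40-fold (-1.77 ± 0.12), and Tnfrsf19, a receptor of the TNF receptor family, fell 3.27-fold (-1.71 ± 0.13). Synpr, a synaptic vesicle protein, fell (-1.68 ± 0.14), as did Tceal7 (-1.56), Tecrl (-1.48), Tm6sf1 (-1.45) and Cyfip2 (-1.45). Myh14, a non-muscle myosin heavy chain, fell (-1.45) at its brightest probe, while a second probe of the gene gave -0.03. The other probes of Cyfip2 gave -1.003 and -0.64.

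**Figure D1:**
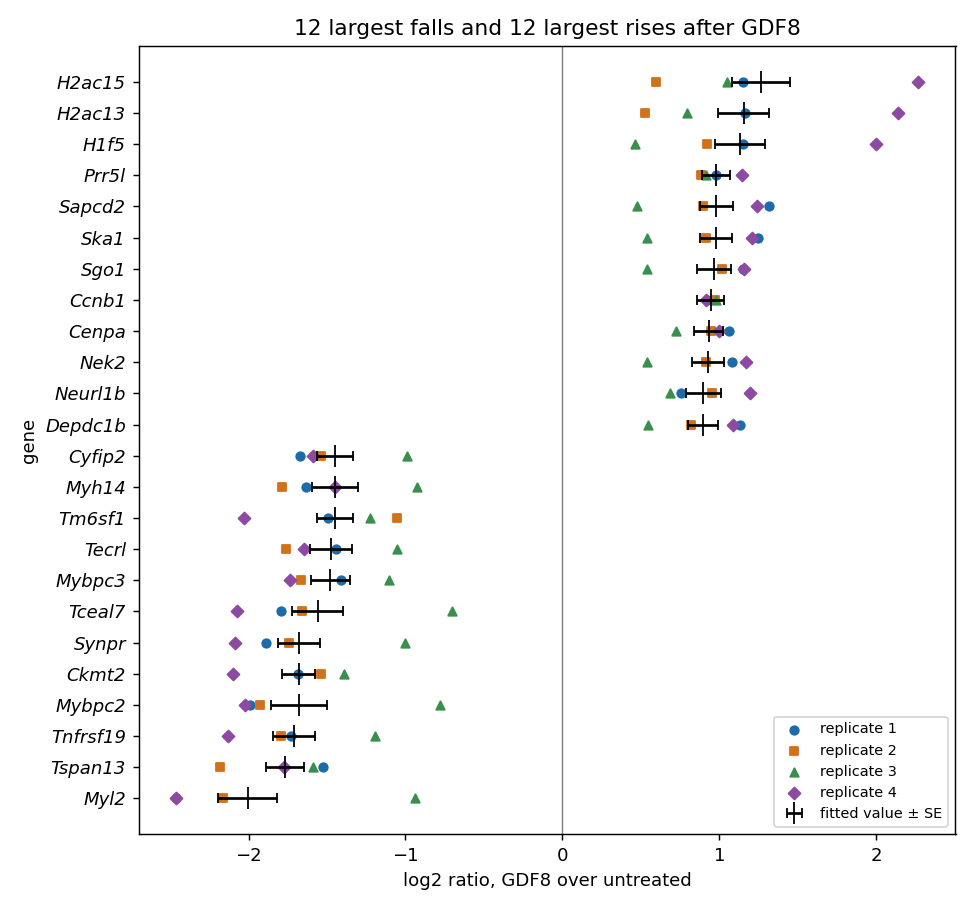
Log2 ratio of GDF8 over untreated cells for the 12 largest falls and the 12 largest rises (horizontal axis), with 1 coloured point per replicate and the fitted value ± SE in black. Falls reach -2.01 in Myl2 and rises reach 1.27 in H2ac15, and the green triangles of replicate 3 lie nearest to 0 for most of the falls and most of the rises.

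The largest rises were in replication-dependent histone genes, H2ac15 (1.27 ± 0.19, 2.40-fold), H2ac13 (1.15 ± 0.16) and H1f5 (1.13 ± 0.16). The H2A genes have near-identical copies, so which copy rose is uncertain. Replicate 4 gave 2.27, 2.14 and 1.99 for these 3, against 0.46 to 1.16 on the other arrays, and without it H2ac15 (0.99, adjusted p = 0.051) and H1f5 (0.92, adjusted p = 0.055) did not pass and were no larger than Sapcd2 (0.999). Losing a call there was not particular to histone genes, since 8 features were higher without replicate 4, against 150 with all 4 arrays. Ska1 and Sgo1, which act at kinetochores and centromeres, rose by 0.98 ± 0.10 and 0.96 ± 0.11, and the mitotic kinase Nek2 by 0.93 ± 0.10. Prr5l, a partner of the mTOR complex, rose by 0.98 ± 0.09, Sapcd2 by 0.98 ± 0.10, Neurl1b by 0.90 ± 0.11 and Depdc1b by 0.90 ± 0.09.

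Of the 41 cell cycle and DNA replication genes measured, 15 were higher, 0 were lower and 26 did not pass; adjusted over the list alone, 28 were higher and 1 was lower. Besides Ccnb1 and Cenpa, the spindle checkpoint kinase Bub1b (0.78 ± 0.09, 1.72-fold) and Aurkb, the kinase of the chromosomal passenger complex (0.80 ± 0.10, 1.74-fold), rose on all 4 arrays. The list median was 0.43, and camera gave an adjusted p of 1.9e-21, against an adjusted p = 0.55 with an estimated correlation. The cyclin D, CDK inhibitor and retinoblastoma list (17 measured, median 0.07) had no member past the threshold and did not pass as a list (adjusted p = 0.15), with Cdk4 at 0.32 ± 0.10, Ccnd1 at 0.29 ± 0.11, Cdkn2d at 0.22 ± 0.10 and Cdkn1c at 0.27 ± 0.12. With probes never saturated that list passed camera (14 measured, median 0.13, adjusted p = 0.023), but not with an estimated correlation (adjusted p = 0.54).

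Of 50 sarcomere genes, 14 were lower and 0 higher (16 lower adjusted over the list alone). Mybpc1 fell 2.54-fold (-1.34 ± 0.10), Tcap, which caps titin at the Z-disc, fell 2.45-fold (-1.29 ± 0.10), and Myot, another Z-disc protein, fell 2.18-fold (-1.13 ± 0.10). The list median was only -0.09, with camera's adjusted p at 1.6e-11 and an adjusted p = 0.55 with an estimated correlation. The median was 0.04 and 0.11 on replicates 1 and 4 (GDF8 in Cy3) and -0.31 and -0.26 on replicates 2 and 3 (GDF8 in Cy5), so its sign turned with the dye orientation. In 33 of the 50 genes the brightest probe was saturated in at least 1 channel. With the brightest probe never saturated, a choice made after seeing the data, 27 genes remained measurable, 15 of them were lower and the median was -0.66 (adjusted p = 0.28 with an estimated correlation). The brightest probes of the same 27 genes gave a median of -0.38. Acta1, Myh3 and Myog, chosen after their values were seen, were saturated in the untreated channel of all 4 arrays, so no ratio is given.

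In muscle energy metabolism, 11 of 23 measured genes were lower and 0 higher (13 lower adjusted over the list alone), and the median was -0.51. Besides Ckmt2, Slc2a4, the insulin-responsive glucose transporter, fell 2.28-fold (-1.19 ± 0.13), Pygm, muscle glycogen phosphorylase, 2.13-fold (-1.09 ± 0.12), and Art1 2.12-fold (-1.08 ± 0.09). Camera gave an adjusted p of 2.0e-12, with an adjusted p = 0.55 with an estimated correlation. The brightest probe was saturated in at least 1 channel in 11 of these genes, and with probes never saturated the median was -0.88 and 10 of 14 were lower. Of 22 calcium handling genes, 3 were lower and 0 higher (12 lower adjusted over the list alone), with a median of -0.29 (camera's adjusted p = 6.2e-10, and adjusted p = 0.55 with an estimated correlation). These were Casq1, the calcium store protein of fast fibres (-1.06 ± 0.13), the calcium pump Atp2a1 (-0.86 ± 0.09) and Trdn (-0.63 ± 0.10). The brightest probe of Trdn was saturated in 2 untreated channels, and its brightest unsaturated probe gave -1.83. Hrc, saturated in 4 untreated and 2 GDF8 channels, did not pass (adjusted p = 0.10). Of the 22 brightest probes 13 were saturated in at least 1 channel, and with probes never saturated the median was -0.50 and 5 of 14 were lower, with Cacna1s (-0.65) and Jph1 (-0.51), chosen after their values were seen, besides those named.

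The acetylcholine receptor and neuromuscular junction list had a median of -0.21 over 19 genes (camera's adjusted p = 3.1e-05, and adjusted p = 0.55 with an estimated correlation). Only Dmd, the dystrophin gene, passed (-0.69 ± 0.09, well above background on 3 of 4 GDF8 arrays), and 4 were lower adjusted over the list alone. With probes never saturated 3 of 15 were lower, Dok7 (-0.55 ± 0.09) and Chrng (-0.71 ± 0.13), both chosen after their values were seen, besides Dmd. Sgcd (-0.48 ± 0.10) and Musk (-0.43 ± 0.12) did not pass. Of 16 myogenic transcription factors, Mef2c alone was lower (-0.95 ± 0.11, 1.94-fold), 3 were lower adjusted over the list alone, and Myf6 (-0.41 ± 0.09), Tead4 (-0.39 ± 0.09) and Six4 (0.27 ± 0.12) did not pass. The list did not pass (median -0.02, adjusted p = 0.15), but did with probes never saturated (median -0.14, adjusted p = 0.019), though not then with an estimated correlation (adjusted p = 0.38). Among 22 adhesion and fusion genes, Cav3, the muscle caveolin, was lower (-0.58 ± 0.10, with 2 untreated channels saturated), Dysf, Adam12 and Neo1 gave -0.32, 0.38 and 0.23 without passing, and the list median was -0.01 (adjusted p = 0.93). With probes never saturated its median was 0.07 over 18 genes, with array medians from -0.09 to 0.04, and 0 genes passed. Camera then gave an adjusted p of 0.84 (0.86 with an estimated correlation), but fry gave 0.0072, upward.

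**Figure D2:**
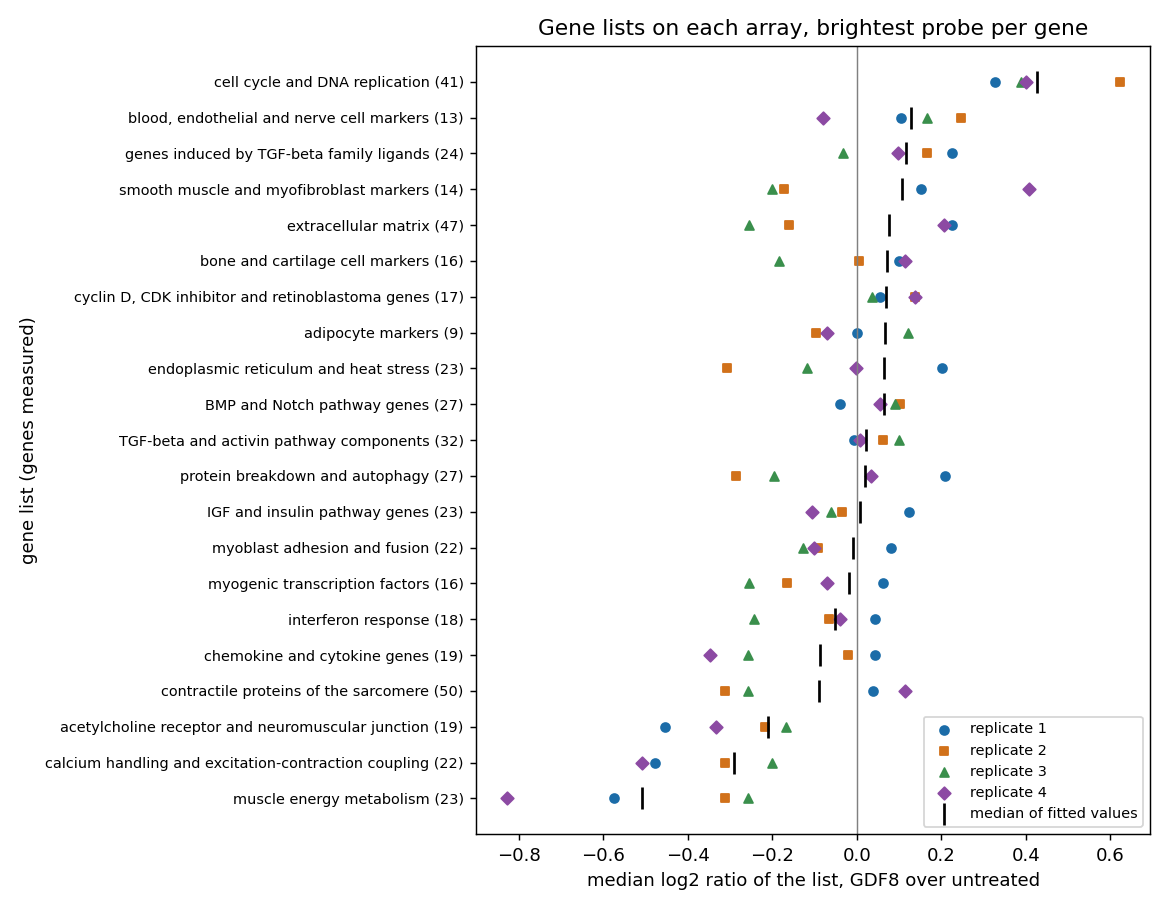
Median log2 ratio of GDF8 over untreated cells for each of the 21 gene lists (number of genes measured in parentheses), with 1 point per replicate and a black bar for the median of fitted values. Energy metabolism, calcium handling and neuromuscular junction lists lie below 0 on all 4 arrays and the cell cycle list above 0 on all 4, while the sarcomere list lies below 0 on 2 arrays.

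The transcript of the added protein's own gene, Mstn, was not well above background: 0 of 4 GDF8 and 1 of 4 untreated channels passed that flag, so it was not tested. No single gene of the 24 measured TGF-beta-induced genes passed (0 also adjusted over the list alone), and 14 of their brightest probes were saturated in at least 1 channel. With probes never saturated 1 of 16 was higher, Pmepa1 (0.52 ± 0.10, chosen after its value was seen), and 5 were higher adjusted over the list alone, and the median was 0.19. As a list they shifted by a median of 0.12, with 20 of 24 positive (camera's adjusted p = 0.0031, and adjusted p = 0.55 with an estimated correlation), and the call was lost without replicate 2 (adjusted p = 0.082) or replicate 4 (adjusted p = 0.084). Spsb1 gave 0.39 ± 0.09, Tgif1 0.28 ± 0.09, Smad7, the inhibitory Smad, 0.24 ± 0.10 and Bhlhe40 0.22 ± 0.09. The TGF-beta and activin pathway list (32 genes, median 0.02, adjusted p = 0.65) and the BMP and Notch list (27 genes, median 0.06, adjusted p = 0.43) had no member past the threshold over all genes. Adjusted over each list alone, 0 passed in the first list, and 2 were higher and 1 lower in the second. Their members with the smallest p were Fst, the follistatin gene (-0.33 ± 0.09), Acvr1b (-0.27 ± 0.10), Smad7 (0.24 ± 0.10) and Inhba (0.30 ± 0.14), and Heyl (0.42 ± 0.09), Id4 (-0.47 ± 0.11), Jag1 (0.35 ± 0.09) and Dll1 (0.33 ± 0.09).

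Of 47 extracellular matrix genes, Col11a1 (0.67 ± 0.09, 1.59-fold) and Tnc, tenascin C (0.53 ± 0.10, 1.45-fold), rose and 0 fell (5 higher adjusted over the list alone), with Col6a2 at 0.39 ± 0.09 and Fmod at 0.71 ± 0.17 not passing. The list median was 0.08 (camera's adjusted p = 0.011, and adjusted p = 0.55 with an estimated correlation), and 36 of the 47 had a saturated channel. Its sign turned with the dye orientation: the list median was 0.23 and 0.21 on replicates 1 and 4 (GDF8 in Cy3) and -0.16 and -0.26 on replicates 2 and 3 (GDF8 in Cy5). Camera no longer passed with the authors' deposited log2 table (adjusted p = 0.084), nor without replicate 2 (0.083) or replicate 4 (0.059), where the median was -0.01. With probes never saturated the median was 0.32 over 29 genes (adjusted p = 0.39 with an estimated correlation).

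Of 19 chemokine and cytokine genes, Ccl11, an eosinophil chemokine (-0.94 ± 0.11), and Il1b (-1.002 ± 0.12) were lower; Il15 (-0.43 ± 0.11) and Cxcl5 (-0.91 ± 0.23) did not pass. The list had a median of -0.09 (camera's adjusted p = 0.0079, and adjusted p = 0.71 with an estimated correlation), and did not pass without replicate 3 (adjusted p = 0.080) or replicate 4 (0.19). Adjusted over the list alone, 6 were lower and 1 higher. Mx2 (-0.75 ± 0.11) was the only one of 18 interferon response genes past the threshold (list median -0.05, adjusted p = 0.11). Small heat shock proteins Hspb3 and Hspb7 fell 2.33-fold and 2.34-fold (-0.76 by a second probe of Hspb7) within a stress list of 23 genes whose median was 0.06, whose mean was -0.03 and which did not pass (adjusted p = 0.97). Trib3, at 1.03 ± 0.21, did not pass (adjusted p = 0.055), but the same probe passed in the fit of probes never saturated (adjusted p = 0.046) and without replicate 3 (adjusted p = 0.027), though not by the methods' t-test (adjusted p = 0.37). With every probe tested on its own it passed (adjusted p = 0.048), as did a second Trib3 probe at 0.77 ± 0.10 (adjusted p = 0.015).

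Grb10, an adaptor of insulin and IGF receptors, was the only one of 23 IGF and insulin genes to pass (-0.89 ± 0.12); it was well above background on 2 of 4 GDF8 arrays, and the list did not pass (median 0.01, mean -0.02, adjusted p = 0.93). In the protein breakdown and autophagy list (27 genes, median 0.02, mean -0.01, adjusted p = 0.94) 0 genes passed, and 2 were lower adjusted over the list alone. Trim63 gave -0.43 ± 0.09, Capn3 -0.46 ± 0.10 and Foxo1 0.23 ± 0.11.

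No list of markers of other cell types passed. Among 9 adipocyte markers the fatty acid carrier Cd36 (-1.06 ± 0.11) and lipoprotein lipase Lpl (-0.71 ± 0.11) fell, genes that muscle also expresses, while Cebpa and Pparg gave 0.14 and 0.09. The list median was 0.07, the mean -0.15 and camera's adjusted p = 0.46. Of 14 smooth muscle and myofibroblast markers Lmod1 fell (-0.48 ± 0.09) and Cnn1 (0.56 ± 0.13) did not pass (list median 0.11, adjusted p = 0.56). Of 16 bone and cartilage markers Dmp1 fell (-0.63 ± 0.10), with Runx2 at 0.36 ± 0.11 by its brightest probe and 0.21, 0.07 and -0.19 by the others (list median 0.07, adjusted p = 0.85). None of 13 blood, endothelial and nerve cell markers passed in limma (list median 0.13, adjusted p = 0.29), where Tubb3 gave 0.56 ± 0.12 and Hba-a1 -0.42 ± 0.10. Adjusted over the list alone, 2 of these 13 were higher and 2 lower. By the same measure 2 bone and cartilage markers were higher and 3 lower, 1 smooth muscle marker was higher and 1 lower, and 2 adipocyte markers were lower.

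**Figure D3:**
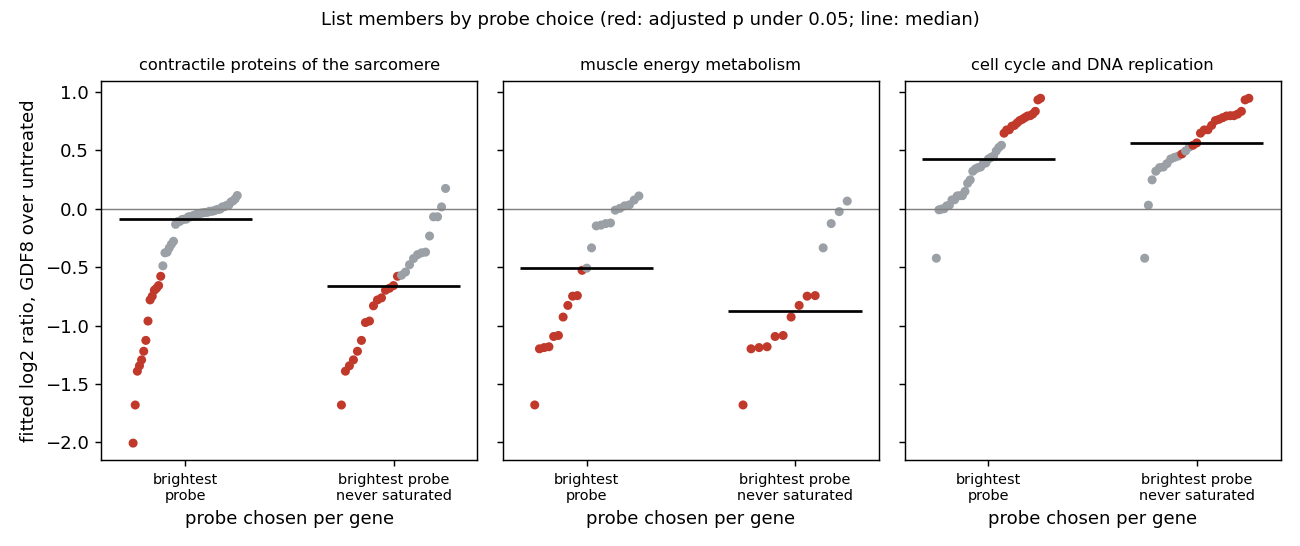
Fitted log2 ratio of GDF8 over untreated cells for the members of 3 lists, with the brightest probe per gene and with the brightest probe never saturated; each point is a gene, red where the adjusted p was under 0.05, and the line is the median. The sarcomere median moves from -0.09 (50 genes) to -0.66 (27 genes) and the cell cycle median from 0.43 (41 genes) to 0.56 (29 genes).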

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

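The test of replicate 3 was chosen after the result was seen. The other tests here were chosen before it, but those of saturation use a probe choice made after seeing the data. For 129 results (named genes, list medians and array measures) the 4 arrays were searched for a value far from the other 3, and 5 stood out, where chance flags about 1 in 20. In Mybpc2 replicate 3 gave -0.78 against -2.02 to -1.93 on the others. In Tgif1 replicate 3 gave 0.37 against 0.24 to 0.25. In Cdkn1c replicate 4 gave 0.76 against 0.09 to 0.12. The median of the adhesion and fusion list was 0.080 in replicate 1 against -0.13 to -0.09. The share of spots flagged as outliers was 1.39% in replicate 1 against 0.09% to 0.19%.

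With probes never saturated, a choice made after seeing the data, the fall of muscle genes was smaller on the array of replicate 3: the sarcomere median was -0.30 there against -0.84, -0.73 and -0.71 on replicates 1, 2 and 4, and the energy metabolism median -0.48 against -1.03, -0.85 and -0.97. The rise of the cell cycle list was 0.42 there against 0.63, 0.81 and 0.52. With the brightest probes the pattern was not seen in the sarcomere list (-0.26 there against 0.04, -0.31 and 0.11) or the cell cycle list (0.39 against 0.33, 0.62 and 0.40), and energy metabolism gave -0.26 against -0.57, -0.31 and -0.83. Compression as large as these muscle differences is argued against by the spike-in transcripts, whose log ratios on array 3 followed the mean of the other arrays with a slope of 0.923 ± 0.011 (SE, 4 spike-in probes without saturation). The same slope was 0.97, 1.01 and 1.09 for arrays 1, 2 and 4. Array 3 thus had the lowest slope, and slight compression stays open. A weaker response of that culture, or an exchange of RNA between its 2 samples, may remain; neither was tested.

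The sarcomere median was nearer to 0 with the brightest probes than with unsaturated ones. In the 10 genes whose brightest probe was saturated and that had another probe never saturated, the median was -0.08 with the first and -0.51 with the second, a difference of -0.44, and 9 of 10 were lower by the unsaturated probe (SD of the differences 0.33). This is consistent with saturated spots compressing the ratios. Leaving out genes also moved the median. With the brightest probes it was -0.09 over all 50 genes, -0.38 over the 27 kept and -0.03 over the 23 left out. Over the 27 kept, the change of probes moved it from -0.38 to -0.66, a difference of 0.28. Of these 27 genes 17 kept the same probe, so that shift rests on the same 10 genes and is no separate evidence. Whether the genes left out respond differently stays open, since they had no unsaturated probe to compare. No biological explanation was tested.

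Across genes never saturated and above background, turned ratios correlated at 0.40 between arrays 1 and 2 and 0.35 between arrays 3 and 4, against -0.06 (1 and 3) and 0.04 (2 and 4), all 4 being pairs of opposite dye orientation; genes are not independent replicates. The contrast of arrays 1 and 2 against 3 and 4 had an SD of 0.17, against 0.09 for the other contrast that treatment and dye leave. A gradient over the array surface is argued against, since means over 128 blocks of rows and columns accounted for 0.45% of its variance. Shared cultures or RNA within these pairs may account for it, but cannot be told apart from other sources: the contrast correlated between 2 probes of a gene with r = 0.29, the other contrast with 0.29 and the treatment effect with 0.75 (4326 genes). If the pairs did share RNA, the arrays would count as 2 replicates, for which 23 features were higher and 172 lower.

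Of the 7 assignments of the labels within arrays that can be fitted beside the dye term, 1 gave as many called features as the real one, which was the real one itself, with 552 against at most 0 in limma for the others (27 to 2155 at an unadjusted p under 0.05, and 2175 for the real one). For lists past the threshold, 1 of the 7 gave as many, again the real one, with 8 against at most 7. With 7 assignments no share under 0.05 can be reached.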

How the results depend on the processing

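The probe choice that avoids saturation and the averaging of array pairs were chosen after seeing the data; the other settings were fixed before the data were examined. Leaving out 1 array gave 8 to 107 features higher and 76 to 322 lower, against 150 and 402 with all 4. All left 1 residual degree of freedom, so this is not why counts were lowest without replicate 4. Features higher numbered 66 without the dye term, and 61 with a fold over 1.6 added, which follows from the added criterion. Without the replicate block, on unpaired single-channel values, 58 were higher and 265 lower, and the cause was not tested. The methods' t-test gave 69 higher and 279 lower at p under 0.05 and a fold over 1.6, and 12 and 75 after Benjamini-Hochberg; of the 69 and 279, 59 and 272 were also called by limma. Averaging arrays 1 and 2 and arrays 3 and 4 into 2 values gave 23 and 172, with fewer values in the fit. With median centring limma's prior degrees of freedom were infinite, so all features had 1 SE (0.18); its p-values and counts (179 higher, 396 lower) are not taken as support. Background correction, offset, the filter on dim probes, the probe choice and the deposited log2 table kept both counts within 1.5 times. Aquantile leaves ratios as they are (largest change 0) and tests nothing here. The deposited log2 table and the scanner log ratio differed by over 0.001 in at most 16 of 17444 features per array and count as 1 alternative. With an estimated correlation the 8 lists that camera called did not pass, with medians as before: sarcomere -0.089, calcium handling -0.29, energy metabolism -0.51, neuromuscular junction -0.21 and extracellular matrix 0.077, and TGF-beta-induced genes 0.12 and cell cycle 0.43 (each adjusted p = 0.55), and chemokines -0.087 (0.71). Camera with an estimated correlation rests on 2 residual degrees of freedom here, so not passing decides little about a list. Fry's adjusted p for these 8 lists was 0.057 to 0.36. The extracellular matrix list also missed the threshold with the scanner log ratio and the deposited table (median 0.0718 in both), and with median centring its median was 0.0743; the cause was not tested. On the 2 arrays with GDF8 in Cy5 medians were -0.18 (extracellular matrix), -0.28 (sarcomere), -0.28 (energy metabolism), 0.031 (TGF-beta-induced genes), -0.26 (chemokines) and 0.56 (cell cycle), and on the 2 with GDF8 in Cy3 0.27 (extracellular matrix), 0.048 (sarcomere), -0.77 (energy metabolism), -0.14 (chemokines) and -0.45 (calcium handling). The sarcomere median was -0.17 with the scanner log ratio and with median centring, the chemokine median -0.16 with the scanner log ratio, and the energy metabolism median -0.33 without the filter on dim probes. Without 1 array, the medians ranged from 0.080 to 0.23 (TGF-beta-induced genes), from -0.0064 to 0.094 (extracellular matrix) and from -0.20 to -0.027 (chemokines). None of the 103 named genes that the rule took changed direction past the threshold under a tested alternative. Many had no call to lose. Of those called, 24 lost it without replicate 4, 16 without replicate 2, 6 without replicate 3 and 4 without replicate 1. The adjusted methods' t-test with a fold over 1.6 lost 33, no replicate block 13 and averaged array pairs 10. Calls lost were 7 without the dye term, 6 with a fold over 1.6 and 3 with the deposited table. Signal over background limits dim genes such as Mstn, and saturation limits bright ones.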

Other observations

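The genes of this part lay outside the rule, except Mef2c, and were chosen after their values were seen. Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 1.43 on the log2 scale (SE 0.09), and the chemokine Cxcl13 by 1.44 (SE 0.11), with the chemokine receptor Cxcr6 by 1.28 (SE 0.10). The GABA receptor subunit gene Gabrb2 (-1.12) and the sulfonylurea receptor Abcc8 (-1.10) fell, as did Camk2b (-1.31), a calcium-dependent kinase. Amhr2, the receptor of anti-Müllerian hormone and so of another TGF-beta family ligand, fell by 1.19 (SE 0.11). Tnni3, the cardiac troponin I gene, which was in no fixed list, fell by 1.40 (SE 0.19).

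Among rises outside the rule, Edn1, the endothelin 1 precursor, rose by 0.72 (SE 0.09), Foxd1, a forkhead transcription factor, by 0.78 (SE 0.09), and Nkd1, an inhibitor of Wnt signalling, by 0.76 (SE 0.10). Hdac9, a histone deacetylase that binds MEF2 proteins, rose by 0.71 (SE 0.10), beside the fall of Mef2c (-0.95). Spc25, a kinetochore protein, rose by 0.83 (SE 0.09) and Pbk, a mitotic kinase, by 0.85 (SE 0.11). Each had the same sign on all 4 arrays. With probes never saturated, Pmepa1, a TGF-beta-induced inhibitor of Smad signalling, was higher by 0.52, and Mki67, a proliferation marker, by 0.80; with the brightest probe Mki67 gave 0.34 and did not pass.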
